A study of Ascaris suum with 12 samples.

How the data were processed

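RNA was extracted with Trizol from frozen, ground germline regions of adult worms, and libraries were made from total RNA after ribosomal depletion with a human, mouse and rat kit, using a TotalScript kit, per the labels' protocols. That depletion kit was made for mammalian RNA, so the amount of ribosomal RNA left in each library can differ. The submitters' processing notes name TopHat2 and Cufflinks, with no version. The genome build, the annotation and whether the library preparation or counting used strand are not given in the sources used here.

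The authors deposited 1 table of RPKM values with 1 decimal, 1 row per transcript and 1 column per germline region. Whether reads or fragments were counted is not stated. Column totals were 1090760 to 1610770, so the values do not sum to a fixed total and depend on which transcripts are abundant. Values of isoforms were treated as estimates that share reads. No column of values was left without a sample, and 15 further columns were empty. The 2 libraries of the mixed sample are not analysed here. Eliminated status, trans-splicing flags, the best expressed transcript and annotations were taken from the table as deposited. A gene was the transcript name without its isoform number. The mark of the best expressed transcript does not follow from the values here. Of 11467 genes with 2 or more transcripts, the marked one had the highest value of its gene in 5067 (44.2%). The values with 1 transcript per gene use this mark, and the comparison of eliminated genes was repeated with the transcript of the highest value. There were 926 genes whose marked transcript is eliminated and 17099 with a retained one, and 5 genes had both kinds of transcript.

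Comparisons used the difference of log2(RPKM + 1), which understates changes of low transcripts. A transcript was called higher or lower at a 4-fold difference with the higher value at 10 RPKM or more. The whole-germline comparison asked for a gap of 2-fold on RPKM + 1 between the lowest value of one sex and the highest of the other, with a floor of 1. Region of highest value used transcripts with a maximum of 10 or more, with the specificity index tau on the same scale. These rules, the 19 gene lists and the rule for named genes were fixed before the data were examined. Named genes had a descriptive annotation, 1 transcript per gene (the highest) and the higher value at 10 or more. They were the 10 largest differences each way for the mitotic regions and for each first against last region, the 3 largest each way per step, the 10 largest gaps per sex, the 2 highest per region and up to 4 members per list. Transcripts of eliminated genes named in the last part of the results, and those of the seminal vesicle set, were chosen after their values were seen.

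The lists were MSP, sperm motility and activation, protein phosphatases, protein kinases, meiotic prophase, DNA replication, mitotic cell cycle, oocyte and eggshell, argonaute and small RNA, germ granule, ribosomal proteins, mitochondrial energy, histones, proteasome, protease inhibitors, and markers of muscle, intestine and yolk, cuticle and neurons. They match words in the annotation. The ribosomal list therefore holds 27 transcripts of 5 genes named for a kinase and 118 transcripts of 48 genes with 28S, 39S or 50S names, which include those of mitochondrial ribosomes. In the neuronal list 302 of 369 transcripts (94 genes) are named for receptors. In the muscle list 74 of 197 (24 genes) are named for titin. For each list the median difference was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, with seed 1. A percentile under 2.5 or over 97.5 was taken as outside the central 95%. Several transcripts of a gene share reads, so the percentile was repeated with the 1 transcript per gene marked best expressed, an alternative added after the data were seen.

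Alternatives were a pseudocount of 0.1, no filter on low values, libraries rescaled by median ratios over 15277 transcripts at 1 or more in every library, removal of the 100 highest transcripts, values summed per gene, a 2-fold threshold, leaving out each region, and other floors. Depth was sought from transcripts under 250 nt as the number of reads that makes their values whole multiples of 1 read. It was reported where the score was at least 1.5 times the 95% point of 200 draws with shuffled lengths, a bound chosen after the scores were seen.

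The rules were tested on simulated data with the levels of the male mitotic region and noise of SD 0.2 on the log2 scale. Of transcripts changed 2, 4, 8 and 16-fold, 0%, 36%, 98% and 98% were called, so a true 4-fold change is often missed. The 2 misses among those changed 8 or 16-fold had a higher value under the filter of 10. No unchanged transcript was called, but noise that small can hardly reach a 4-fold difference. The simulation therefore gives no rate of false calls for these libraries, whose noise is unknown without replicates. Work was done in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.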

Results

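The series profiled RNA along the germline of Ascaris suum, a large parasitic roundworm of the pig intestine that discards part of its genome from somatic cells early in development, a process called programmed DNA elimination. Adult worms were dissected into 5 regions of the male germline (mitotic region, spermatogenesis, post-meiotic region, seminal vesicle and spermatids) and 5 of the female germline (mitotic region, early pachytene, late pachytene, diplotene and oocyte). Each region was 1 library, so no difference below has a replicate check, no p-value is given, and transcripts were named by a rule of size. The other 2 samples, 5' end libraries of a mixed sample, had no expression column and entered no comparison. The table held RPKM values, which scale reads by transcript length and library size, for 61820 transcripts of 18025 genes. Coordinates are those of the table, and its genome build is not given in the sources used here.

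Between 24126 transcripts (seminal vesicle) and 44736 transcripts (male mitotic region) reached 1 RPKM. The seminal vesicle library listed 25.5% of transcripts at 0, against 8.10% to 15.7% in the other 9 libraries. A few transcripts took much of each total. The 100 highest held 21.7% of the summed values in the male mitotic region and 66.0% in the seminal vesicle. These shares ignore transcript length. The highest transcript in spermatids, AgB01_g790_t02 (dyslexia-associated protein, 18502 nt), was at 39946.6 RPKM. Its RPKM times length in kb was 739092 in spermatids and 570274 in the post-meiotic region. In the male mitotic region it was 50203.3, and in the seminal vesicle 10597.9. Isoforms share reads, so its share of each library is not given. Other values in these libraries depend on it. Depth could be read from the steps between low values in 4 libraries, at about 9000000 reads or fragments in diplotene, 23100000 in the oocyte, 27000000 in the male mitotic region and 27900000 in spermatids. It was not resolved in the other 6.

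Early and late pachytene were nearly the same library in content, with a Pearson r of 0.996 across 55167 transcripts on the log2(RPKM + 1) scale. The female mitotic region was close to both (r = 0.958 and 0.962), and diplotene was closest to the oocyte (r = 0.889). In the male, the seminal vesicle and spermatids had r = 0.813, and the mitotic region and spermatogenesis r = 0.774. Spermatogenesis stood farthest from the female libraries, with r of 0.0755 against the oocyte and 0.153 against the female mitotic region. The median r was 0.670 within the male germline, 0.746 within the female germline and 0.513 between the sexes. Transcripts are not independent replicates, so these values only describe the libraries.

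**Figure D1:**
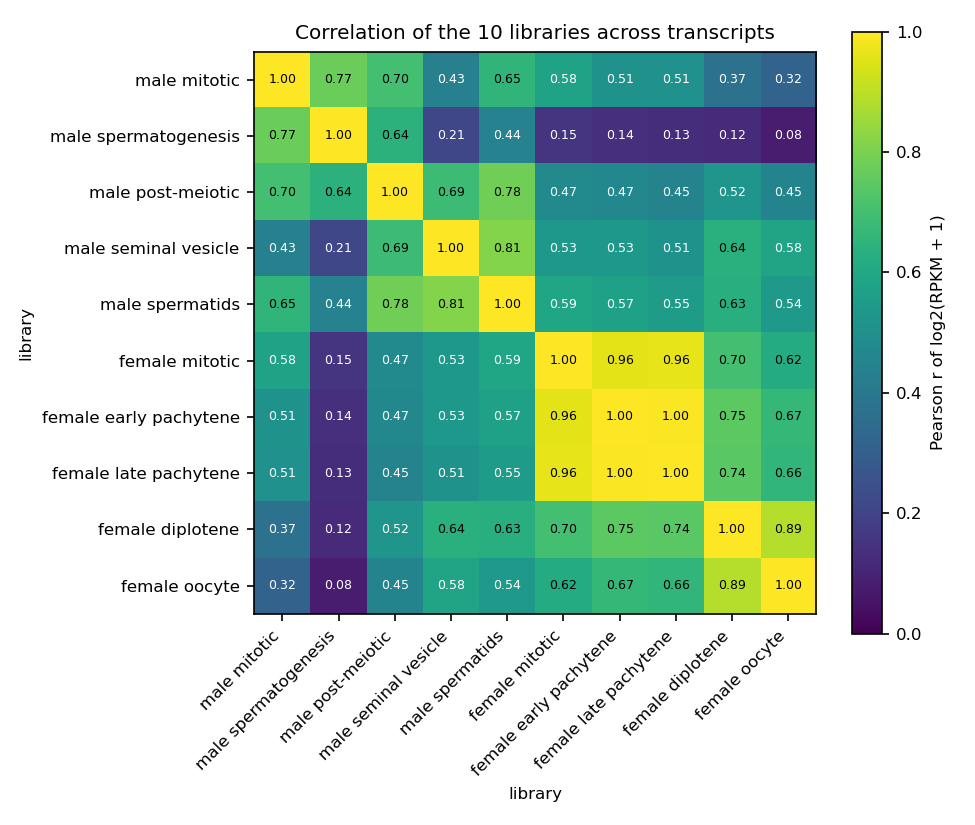
Pearson r between the 10 libraries (both axes, 1 library per region) across transcripts at 1 RPKM or more in at least 1 library, on the log2(RPKM + 1) scale. The 3 early female regions form a block with r from 0.958 to 0.996.

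The region named mitotic in both sexes differed in sperm genes. A set of 49 transcripts abundant in spermatogenesis was at a median of 25.3% of its spermatogenesis value in the male mitotic library. Of these, 17 lay within 1.2-fold of that ratio. Whether this RNA came from mitotic germ cells was not tested. Major sperm protein (MSP), the cytoskeletal protein that drives the crawling of nematode sperm, was at 9162 RPKM in the male and 20.7 in the female for transcript AgE02_g017_t02 (MSP isoform beta, scaffold AgE02, positions 206233 to 441716, 3 exons, a model that spans the paxillin gene), a difference of 8.72 on the log2(RPKM + 1) scale. The MSP fiber protein transcripts AgR017_g212_t01 (MFP2b, scaffold AgR017, 3243856 to 3246259, 5 exons, 941.4 against 1.1), AgR003_g210_t01 (MFP1-beta, 762.8 against 1.2) and AgR032_g081_t02 (MFP2c, 484.4 against 1.0) were also higher in the male, as was paxillin, an adaptor of cell adhesion sites (AgE02_g028_t03, AgE02, 379010 to 387782, 7 exons, 522.9 against 0.7). Higher in the female were low-density lipoprotein receptor-related protein 2 (AgR040X_g050_t01, 318.8 against 1.1), the zonadhesin transcript AgR006_g331_t05 (781.1 against 5.1) and chondroitin proteoglycan 2 (AgR005_g202_t04, 11169.5 against 156.3). Chondroitin proteoglycans are components of nematode eggshells. Acetyl-CoA acetyltransferase A (AgB10_g116_t01) was at 144.0 RPKM in the female and 0.8 in the male.

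By list, 99 of 130 MSP transcripts (36 of 48 genes) were at least 4-fold higher in the male and 0 were lower. The sperm motility and activation list had 61 of 104 higher and 0 lower. Protein phosphatases had 310 of 949 higher and 72 lower, protein kinases 348 of 1524 higher and 60 lower, and the proteasome 51 of 208 higher and 0 lower. Their medians lay at percentile 100 of 10000 random lists matched on expression, and at 98.1 (kinases) or more with 1 transcript per gene. Ribosomal proteins also lay at percentile 100, with a median difference of 0.62 and 3 transcripts higher and 3 lower. Protease inhibitors, with 26 of 54 transcripts lower in the male and 4 higher, and the neuronal markers, with 29 of 369 lower and 11 higher (11 and 5 with rescaled libraries), both lay at percentile 0. The mitotic cell cycle list lay at percentile 100 with 17 of 480 higher and 2 lower (9 and 0 with rescaled libraries), but 191 of its transcripts carry the name of a spindle- and centromere-associated protein. The oocyte and eggshell list had 9 of 176 transcripts higher and 34 lower in the male, or 12 and 11 with rescaled libraries, and its percentile of 1.5 became 12.04 with 1 transcript per gene and 5.05 with rescaled libraries. Of its transcripts, 77 are named for gld genes and 63 for low-density lipoprotein receptors. The DNA replication (65.5), meiotic prophase (62.3), argonaute and small RNA (72.1), germ granule (83.2), histone (66.9) and mitochondrial energy (83.3) lists lay inside the central 95% of random lists. So did the markers of muscle (11.5), of intestine and yolk (13.4, but 0.335 for the 13 genes with 1 transcript each) and of cuticle (4.86, but 0.03 with rescaled libraries).

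Altogether 4709 transcripts (1381 genes) were at least 4-fold higher in the male mitotic region and 2999 (937 genes) lower, with the higher value at 10 RPKM or more. Isoforms of a gene share reads, so counts of transcripts are not counts of independent events. Rescaling by median ratios gave 3615 higher and 1518 lower, while a 2-fold threshold turned the balance to 6532 higher and 7473 lower.

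**Figure D2:**
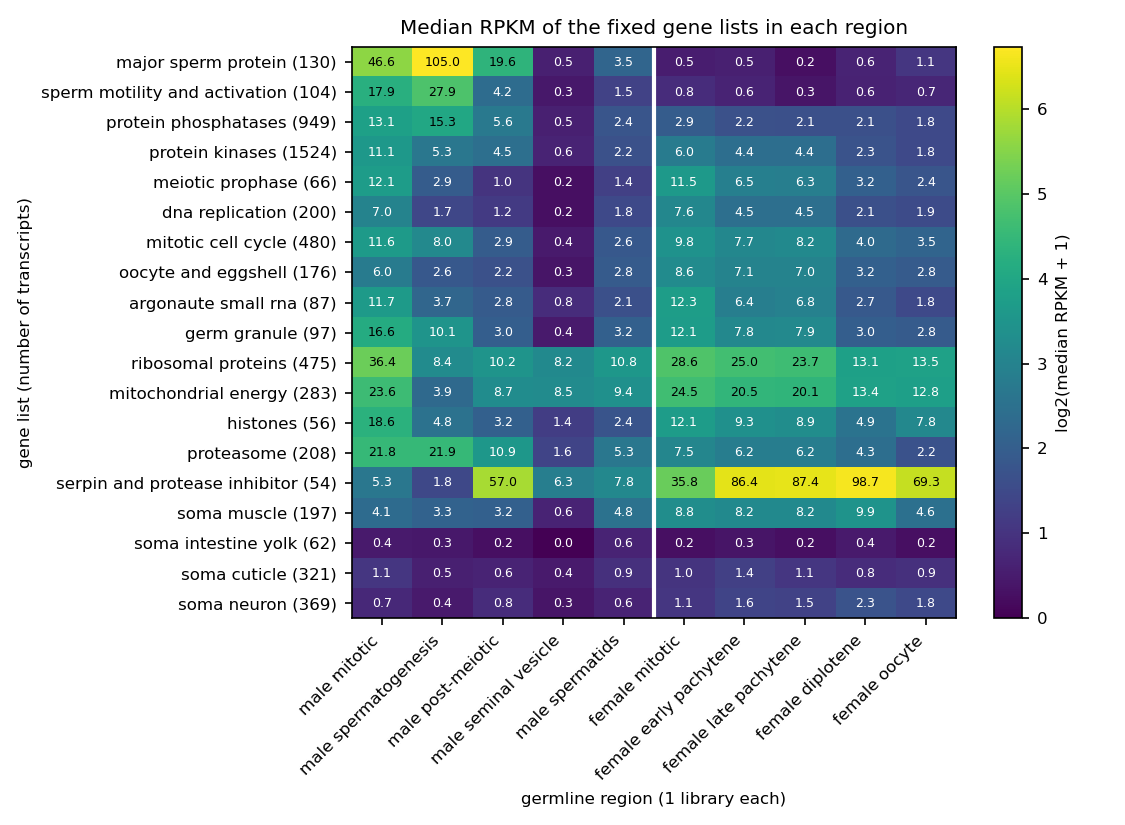
Median RPKM (numbers, and color on the log2(median + 1) scale) of the 19 fixed gene lists (rows, with their number of transcripts) in each of the 10 regions (columns). The MSP list peaks at 105.0 in spermatogenesis and stays at 1.1 or less in each female library.

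Along the male germline, the median of the MSP list was highest in spermatogenesis, at 105.0 RPKM, against 46.6 in the mitotic region, 19.65 in the post-meiotic region and 0.5 in the seminal vesicle. Not every sperm gene followed it, as sperm-specific protein ZC168.6 (AgR086_g007_t01) was at 6705.8 in spermatogenesis and 8185.7 in the post-meiotic region. Abundant MSP transcripts fell less than the list median in that step. AgE02_g017_t02 was at 19599.5 and 14475.6, AgE02_g037_t01 at 14397.9 and 10842.6, and AgB02_g504_t01 at 13039.6 and 9492.4. Of the whole list, 65 of 130 transcripts were at least 4-fold lower. From the mitotic region to spermatogenesis, 34 of 130 MSP transcripts were at least 4-fold higher and 0 lower (113 and 0 with rescaled libraries), while with 1 transcript per gene 90 of 142 ribosomal protein genes and 46 of 104 mitochondrial energy genes were lower and 0 higher. The direction of these last counts was turned by rescaling, after which 33 of 475 ribosomal protein transcripts were higher and 1 lower, and 9 of 283 mitochondrial energy transcripts higher and 4 lower. Against random lists both stayed low, at percentile 0 as deposited and with rescaled libraries. Kinesin-like protein KIF13A (AgB14_g100_t19) was at 12.6 RPKM in the mitotic region and 200.9 in spermatogenesis. Niemann-Pick C1 protein, a lysosomal cholesterol transporter (AgR001_g141_t02), was at 47.9 and 1.1.

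In the post-meiotic region the antimicrobial peptides cecropin-P3 (AgB19_g010_t05, 1262.7 against 1.1 RPKM in spermatogenesis) and cecropin-P1 (AgB19_g012_t01, 427.7 against 0.2) were higher, and so was actin-2 (AgB13X_g040_t02, 3585.5 against 7.5). Protease inhibitors were higher in 28 of 54 transcripts and lower in 1 (percentile 100, or 95.05 with 1 transcript per gene). MSP transcripts were at least 4-fold lower in 65 of 130 and germ granule transcripts in 50 of 97 (8 of 18 genes), with 0 higher in both. Protein phosphatase transcripts were lower in 330 of 949 (534 with rescaled libraries) and higher in 48. Each list lay at percentile 0. With 1 transcript per gene germ granule genes lay at 0.63 and the other lists at 0. The germ granule list is mostly tudor domain genes, which make up 91 of its transcripts.

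The seminal vesicle, where sperm are stored, carried C-type lectin transcripts such as AgB03_g440_t01 (3560.3 RPKM, against 243.4 in the post-meiotic region) and a trypsin family transcript (AgR004_g242_t01, 389.6 against 25.8). Among the 1000 other transcripts at 100 RPKM or more there, 1 lay more than 1.2-fold below a ratio of 7.17% in the post-meiotic library. The largest differences the other way rest on transcripts listed at exactly 0 in the seminal vesicle, such as ribosomal protein S6 kinase 2 alpha (AgR035X_g089_t08, 12566.1 in the post-meiotic region and 15939.9 in spermatids) and glutamate dehydrogenase (AgB10_g192_t03, 451.4 and 20 RPKM). Of the other transcripts of that kinase gene, the highest was AgR035X_g089_t07. It was at 186.7 RPKM in the post-meiotic region, 201.7 in spermatids and 41.2 in the seminal vesicle. Glutamate dehydrogenase transcripts not listed at 0 were lower there too. AgB10_g192_t04 was at 440.9 in the post-meiotic region and 2.9 in the seminal vesicle, and AgB10_g192_t05 at 387.7 and 2.7. In all, 246 transcripts of 246 genes were listed at 0 there with 10 RPKM or more in both neighbouring regions, and each had another transcript of its gene above 0. In spermatids the OV-17 antigen (AgR006_g149_t01, 1254.8 against 2.2 in the seminal vesicle) and a cuticular collagen (AgR049_g018_t01, 1355.7 against 6.3) were higher. TAR1, an open reading frame antisense to ribosomal RNA genes in yeast, was lower (AgR002_g272_t01, 425.3 against 36150.8). Its locus (AgR002, 4590518 to 4619042) holds overlapping transcripts on both strands, some named for regulator of rDNA transcription protein 15. Ribosomal RNA left after depletion was not tested as a source of their values.

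The 4 male steps had 1446 higher and 6378 lower transcripts, 3621 and 6355, 985 and 4061, and 1696 and 219, in order. A 2-fold threshold gave the last step a more even balance, with 2327 higher and 1620 lower. So did values summed per gene for the second step, with 1731 higher and 1866 lower. The balance of the first 2 steps depended on scaling. After median-ratio rescaling they had 9903 higher and 225 lower, then 2250 higher and 11981 lower. The rescaling divided libraries by factors of -1.20 (spermatogenesis) to 1.04 (female mitotic region) on the log2 scale. Values of spermatogenesis were thus raised and those of the female mitotic region lowered. A direction for the bulk of transcripts is therefore not given. Without the seminal vesicle, spermatids against the post-meiotic region had 897 higher and 2801 lower.

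**Figure D3:**
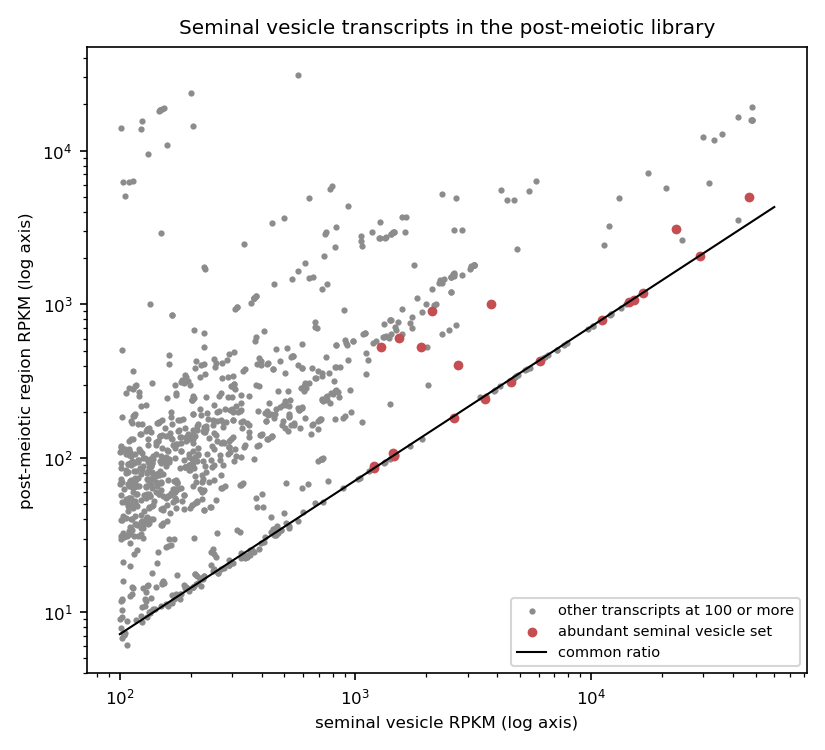
Value in the post-meiotic region against value in the seminal vesicle (RPKM, log axes, 1 point per transcript at 100 or more in the seminal vesicle), with the set that defined the common ratio in red and the ratio of 7.17% as a line. Of the 1000 other transcripts (grey), 1 lies more than 1.2-fold below the line.

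**Figure D4:**
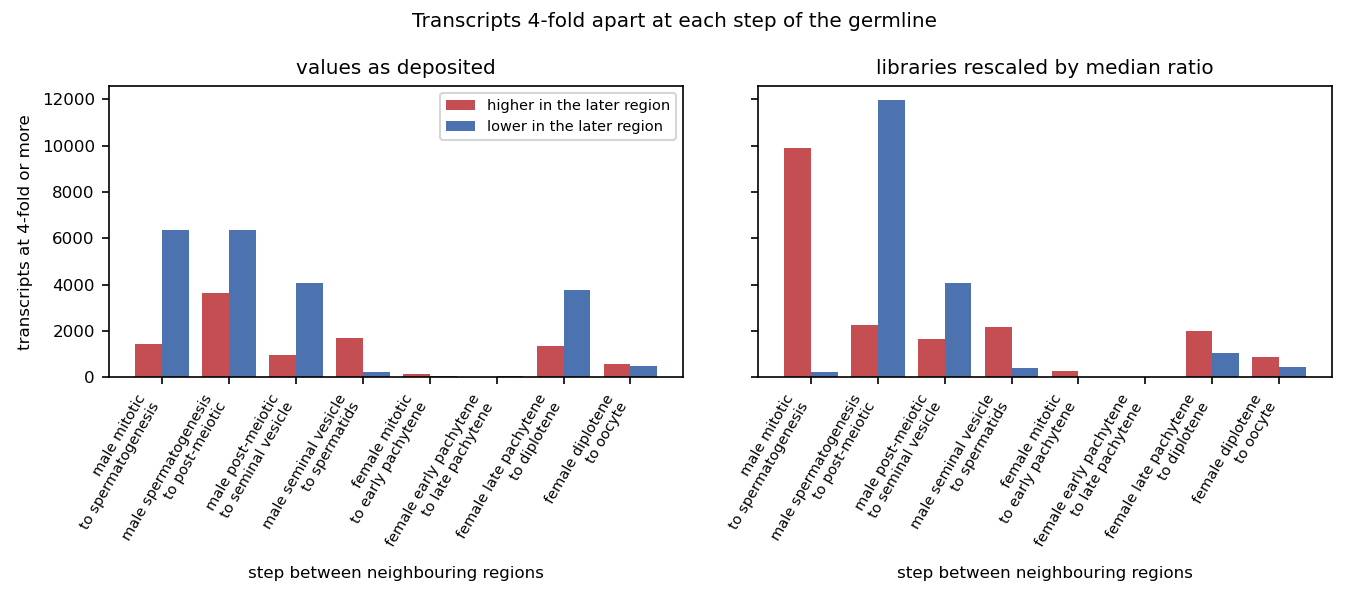
Number of transcripts at least 4-fold higher (red) or lower (blue) in the later of 2 neighbouring regions, for values as deposited (left) and after median-ratio rescaling (right). The first male step changes from 1446 higher and 6378 lower to 9903 higher and 225 lower.

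Along the female germline, the large step was from late pachytene to diplotene. Ovarian abundant message protein was at 14966.1 RPKM in late pachytene and 42.9 in diplotene for AgB24_g040_t07 (scaffold AgB24, 752757 to 754978, 4 exons). Thioredoxin domain-containing protein 12 (AgR002_g112_t01) was at 0.3 and 29453.1 RPKM, an abf-2-like antibacterial factor (AgR032_g086_t01) was listed at 0 and at 7299.6, and a C-type lectin (AgR019X_g188_t02) was at 0.1 and 5580.2. In this step 1356 transcripts (467 genes) were at least 4-fold higher and 3782 (1111 genes) lower, or 1989 and 1033 after median-ratio rescaling. Argonaute and small RNA genes had 13 of 87 transcripts lower and 0 higher (4 and 0 with rescaled libraries), at percentile 0, or 0.41 with 1 transcript per gene. Muscle markers, a list for tissue other than germ cells, had 34 of 197 higher and 14 lower, at percentile 100.

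The steps before it were small. From the female mitotic region to early pachytene, 147 transcripts were higher and 65 lower (254 and 21 after rescaling), and a 2-fold threshold turned this to 1255 higher and 2262 lower. The 3 largest differences toward lower values were in transcripts named for the retrovirus-related Pol polyprotein of a type 1 retrotransposon, such as AgR011_g308_t01 at 467.2 and 15.9 RPKM, and the gut transcription factor elt-2 (AgR001_g424_t11) was at 1.2 and 15.8. From early to late pachytene 0 were higher and 39 lower, in 9 genes, and 20 of the 39 had their highest value in the seminal vesicle or spermatids. The 3 named ones are abundant in the seminal vesicle library, such as cuticle collagen 12 (AgB01_g561_t01), at 54.9 and 4.9 RPKM and at 14536.2 in the seminal vesicle. Without values under 1% of the seminal vesicle or spermatogenesis value, 2 transcripts remained in the count. From diplotene to oocyte 571 were higher and 508 lower (879 and 449 after rescaling, 769 and 440 without the 100 highest transcripts), and a 2-fold threshold turned this to 1936 higher and 2300 lower. Histone H2B (AgB03_g235_t03) was at 375.1 and 0.9, and FACT complex subunit SSRP1, a histone chaperone (AgB08X_g063_t01), at 3.7 and 115.2. The histone list had 2 of 56 transcripts higher and 8 lower in this step (7 and 8 with rescaled libraries), while its median went the other way, from 4.9 to 7.75 RPKM, at percentile 100 of random lists. Muscle markers had 4 of 197 transcripts higher and 18 lower in this step, and 0 of 369 neuronal markers were called. Both lists lay at percentile 0.

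Comparing the ends of each germline, spermatids had 68 of 321 cuticle transcripts at least 4-fold higher than the male mitotic region and 2 lower. Most of that list passed no call. Its median was 1.1 RPKM in the mitotic region and 0.9 in spermatids, or 0.644 and 1.25 with rescaled libraries, at percentile 100 of random lists in both. Higher in the same comparison were OV-17 antigen (1254.8 against 0.7 RPKM), asparagine synthetase (AgB13X_g025_t01, 369.0 against 0.1) and the C-type lectin AgB03_g439_t01 (17879.0 against 46.6). The lower transcripts were a sperm-specific protein (AgR028_g102_t01, 1.7 against 133.0), the translational regulator cytoplasmic polyadenylation element-binding protein 1 (AgR002_g136_t01, 0.3 against 61.1), innexin unc-7, a gap junction protein (AgR018X_g181_t02, 3.5 against 181.1), and a Y-box factor (AgR006_g127_t05, 0.6 against 61.6). MSP was lower in 60 of 130 transcripts, histones in 34 of 56 transcripts and the germ granule list in 51 of 97 transcripts, with 0 higher in each of the 3 lists. After rescaling these were 42, 6 and 16, with 2 germ granule transcripts higher. Intestine and yolk markers had 14 of 62 transcripts higher and 0 lower (percentile 99.98, or 96.7 with 1 transcript per gene). Muscle markers had 12 of 197 higher and 51 lower (41 and 1 with rescaled libraries) and neuronal markers 26 of 369 higher and 14 lower (31 and 3 with rescaled libraries), both at percentile 100.

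In the oocyte, transcripts named for an antibacterial factor, a protease and a transthyretin-like protein led among those with a descriptive annotation. A hypothetical protein (AgR040X_g056_t01) was far higher there, at 159522 RPKM against 0 in the mitotic region. The abf-2-like factor was at 15664.7 RPKM and listed at 0 in the mitotic region, a trypsin family transcript (AgB03_g445_t01) was at 26821 against 4.1, and transthyretin-like protein 16 (AgR004_g294_t03) at 18622.5 against 3.3. Type 1 retrotransposon Pol transcripts made up 7 of the 10 largest differences the other way, such as AgR011_g309_t04 (0.3 against 2343.1). The list of protease inhibitors had 15 of 54 transcripts higher and 0 lower (28 and 0 with rescaled libraries), led by serpin B6 (AgR031_g028_t01, 4388.7 against 1.1), while the argonaute list had 39 of 87 lower and 0 higher (13 and 0 with rescaled libraries) and the DNA replication list 22 of 200 lower and 2 higher, which turned to 3 lower and 5 higher with rescaled libraries. Markers of other tissues moved in the same comparison, muscle with 31 of 197 transcripts higher and 70 lower (39 and 33 with rescaled libraries) and neurons with 12 of 369 higher and 21 lower (30 and 4 with rescaled libraries), both at percentile 100. Spermatids against the mitotic region had 1422 higher and 8926 lower transcripts, and the oocyte against its mitotic region 1638 and 8820. After median-ratio rescaling these were 2333 and 2487, and 3709 and 2032. Without the 100 highest transcripts they were 1814 and 5480, and 2188 and 5749.

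Across whole germlines, 281 transcripts (123 genes) had a lowest male value at least 2-fold above the highest female value, and 1465 (536 genes) the converse. Sperm-specific protein ZC168.6 (AgR086_g007_t01) ranged from 87.5 to 8185.7 RPKM in the male regions and from 1.6 to 7.9 in the female regions. A transcript annotated as gld-1, named in the table as a female germline tumor suppressor (AgR001_g389_t01), was at 11.3 to 381.2 in the male and at 0.4 or less in the female. Chondroitin proteoglycan 3 (AgR005_g431_t01) was at 854.4 or more in each female region and at 12.5 or less in each male one, and a metalloproteinase inhibitor (AgR008_g221_t01) at 117.2 or more against 3.2 or less. With any gap and no floor, 7169 transcripts (11.6%) did not overlap between the sexes, where chance orderings of 10 independent values give 0.794%. The regions of a germline are not independent (r up to 0.996), so that share is not a fair no-change value here. The balance rested on the seminal vesicle. Without it, it turned to 2255 transcripts higher in the male and 1593 in the female. Without the male mitotic region 308 were higher in the male and 2447 in the female.

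Of 32863 transcripts that reached 10 RPKM, 9079 (27.6%) were highest in the female mitotic region and 7461 (22.7%) in spermatogenesis. After rescaling these counts were 1782 and 14429. Of the named transcripts with their maximum there, HUWE1, a ubiquitin ligase, was the highest in the female mitotic region (AgE03_g001_t03, 2422 RPKM), MSP isoform beta in spermatogenesis (AgE02_g017_t02, 19599.5), and regulator of rDNA transcription protein 15 in the seminal vesicle (AgR002_g269_t05, 48335.9). The last of these lies in the locus of the TAR1 transcript above, and leftover ribosomal RNA was not tested as its source. A specificity index tau of 0.9 or more was found for 262 transcripts, 106 of them highest in spermatids and 78 in spermatogenesis. That count was 1021 after rescaling, 1670 with a maximum of 1 RPKM or more and 71 on the log2(RPKM + 0.1) scale.

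The table also marks genes that are removed from somatic cells. Of 926 such eliminated genes, 803 (86.7%, 95% exact binomial interval 84.4 to 88.8) reached 1 RPKM in the male mitotic region and 726 (78.4%, 75.6 to 81.0) in spermatogenesis, against 62.3% and 49.4% of 17099 retained genes. In the oocyte it was the reverse, with 36.0% (32.9 to 39.1) of eliminated and 56.9% of retained genes. The seminal vesicle went the same way as the oocyte, with 10.7% and 38.0%, so the reversal was not limited to the female. Shares differed little in the post-meiotic region (57.7% and 55.7%) and in spermatids (54.8% and 51.4%). Among those that reached 10 RPKM, 423 of 573 eliminated genes (73.8%, 70.0 to 77.4) were highest in the male mitotic region or in spermatogenesis, against 31.7% (30.7 to 32.8) of retained genes. They included 4 genes of MSP isoform beta, paxillin, a pyruvate dehydrogenase E1 alpha subunit (AgE58_g002_t03, 2234.3 RPKM in spermatogenesis) and myosin-VI (AgE46_g003_t05, 473.7), while tubulin alpha-2 (AgE01_g014_t01) was at 478.4 in late pachytene and 28.4 in spermatogenesis. With the transcript of each gene that was highest in these libraries the shares were 72.6% and 32.1%. The intervals cover counting of genes only. This comparison was chosen after the columns of the table were seen, and so were the values given with 1 transcript per gene.

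**Figure D5:**
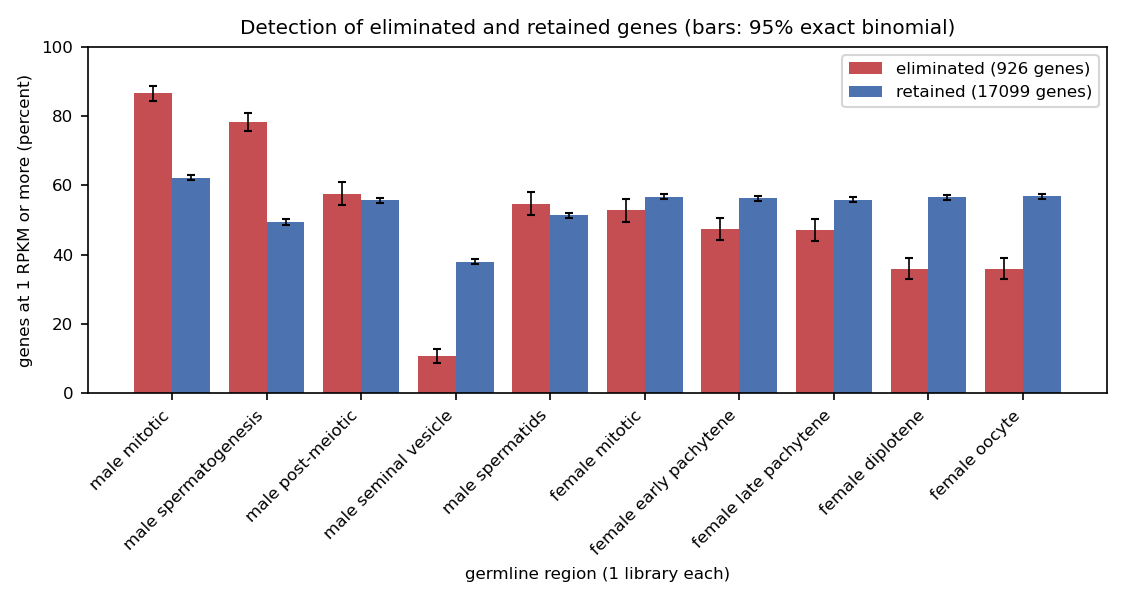
Share of eliminated (red, 926) and retained (blue, 17099) genes at 1 RPKM or more in each region, 1 transcript per gene, with 95% exact binomial intervals as error bars. Eliminated genes are at 86.7% in the male mitotic region, at 10.7% in the seminal vesicle and at 36.0% in the oocyte.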

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

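The 4 lists below were picked out because their last region against the mitotic region went opposite ways in the male and the female, relative to random lists of the same size and expression. The difference between the sexes was not tested, since each region is 1 library. Values are the median difference of the list minus that of the random lists, on the log2(RPKM + 1) scale. The MSP list was at -0.8337 in spermatids and at 1.2619 in the oocyte, and the sperm motility and activation list at -1.2762 and 0.5142. Both have female medians near the lower end of the scale, with MSP at 0.45 RPKM in the female mitotic region and 1.1 in the oocyte. The set of 49 transcripts abundant in spermatogenesis, MSP among them, was at 1000 RPKM or more there. In the seminal vesicle its members were at 1.33% or less of that value, with 45 above 0. Not all are particular to sperm, as heat shock protein 70 b2 (AgR033_g090_t14) was at 1104.9 in spermatogenesis and 1883.3 in the female mitotic region. The set had low median ratios to spermatogenesis in these 2 female libraries. They were 0.0743% in the female mitotic region and 0.162% in the oocyte, with 13 and 10 transcripts within 1.2-fold. The source of such traces was not tested. Protein phosphatases were at -0.7395 and 0.2999, and ribosomal proteins at -0.245 and 0.2577. With rescaled libraries the oocyte values of sperm motility (percentile 92.5) and protein phosphatases (percentile 30.8) lay inside the central 95% of random lists. With 1 transcript per gene the ribosomal proteins in spermatids (percentile 4.595) and the protein phosphatases in the oocyte (percentile 88.6) lay inside it too, so these 2 lists no longer lay outside it on opposite sides. Without names of kinases or of 28S, 39S or 50S proteins, an alternative chosen after the data were seen, the ribosomal list still did, at percentile 1.96 in spermatids and 99.94 in the oocyte. No explanation was tested for these lists.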

How the results depend on the processing

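No paired analysis was possible because each region is 1 library, with no number that pairs male and female regions. The alternatives with 1 transcript per gene, without values under 1% of a male source, without the transcripts listed at 0 in the seminal vesicle, and those of eliminated genes were chosen after the data were seen. Counts here are totals of higher and lower transcripts, in the order M against F mitotic, the 4 male steps, the 4 female steps, spermatids against mitotic and oocyte against mitotic. The cause of a change was not tested, except that counting genes gives fewer items and a lower threshold or floor more. With 1 transcript per gene the counts were 1978, 2149, 2428, 1256, 494, 78, 9, 1309, 352, 2506 and 2597, the whole-germline counts 100 (male) and 456 (female), the regions of highest value 1150, 1731, 391, 474 and 144 (male) and 2170, 834, 360, 433 and 629 (female), and the lists outside the central 95% were 5, 6, 8 and 6 in the female steps, down from 12, 10, 15 and 11. Summed per gene the counts were 2673, 3481, 3597, 2519, then 137, 12, 1916, 504, 3882 and 3451 from the first female step on, and 175 and 555 for the whole germlines. With a 2-fold threshold they were 14005 (M against F), 15022 and 3947 (first and last male step), 3517, 12887 and 4236 (mitotic to early pachytene, late pachytene to diplotene, diplotene to oocyte), 17412 and 16995. With that threshold M against F turned to 6532 higher and 7473 lower, the first female step to 1255 and 2262, and the last to 1936 and 2300. After median-ratio rescaling the counts were 5133 (M against F), 3022 (late pachytene to diplotene), 4820 and 5741, with 523 higher in the male germline. Regions of highest value were then 696 (male mitotic), 14429 (spermatogenesis), 3699 (seminal vesicle), 964 (spermatids), 1782 (female mitotic) and 3800 (oocyte), 1021 transcripts had tau at 0.9 or more, and 81.8% of eliminated and 38.6% of retained genes were highest in the first 2 male regions. With all transcripts the retained share was 33.5% and the median r between the sexes 0.570. With a maximum of 1 or more the regions of highest value were 10128 (male mitotic), 2686 (post-meiotic), 1380 (spermatids), 2456 (late pachytene), 3189 (diplotene) and 4630 (oocyte), tau passed in 1670, and the retained share was 34.3%. Tau on log2(RPKM + 0.1) passed in 71. A floor of 0.1 gave 54629 (spermatogenesis) and 46060 (seminal vesicle) detected transcripts, and a floor of 10 gave 19691, 12759, 10283, 6420 and 7567 (male) and 19595, 17210, 17086, 9917 and 9160 (female). Without the filter on low values the last 2 male steps had 9142 and 4192. A pseudocount of 0.1 gave 323 in the first female step and 485 for the male germline. Any gap above 0 with the floor of 1 gave 723 (male) and 4282 (female). Without the male mitotic region 2447 were higher in the female, and without the seminal vesicle the balance turned to 2255 in the male and 1593 in the female. Early to late pachytene had 18 without the 100 highest transcripts and 2 without values under 1% of a male source. No result was reversed by its verdict rule, which for counts reads totals and not the balance of higher and lower, and the balance turned where stated here and in the comparisons. Among the 4 libraries with a resolved depth, diplotene had the lowest, at 9000000 reads or fragments, and the other 6 cannot be ranked.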

Other observations

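Transcripts with their maximum in spermatogenesis differed from the rest in how their 5' ends were flagged in the table. Of these 7461 transcripts, 31.9% were flagged as trans-spliced to the spliced leader and 36.3% as found by the cap-based 5' end library, against 49.8% to 71.8% and 11.4% to 23.6% for the other 9 regions. Eliminated transcripts made up 22.2% of them, against 0.0655% (diplotene) to 11.0% (male mitotic region) for the other 9 regions. The mixed 5' end sample does not say from which region a flagged end came.

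Of the tests below, those of the transcripts listed at 0, the counts in other libraries at the same bound, and those of 1 scaffold and of scaling for eliminated genes, were chosen after the result was seen. The 21 transcripts that defined the seminal vesicle set were at 1000 RPKM or more there and at least 50-fold over spermatogenesis.

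Of the 21 transcripts, 13 lay within 1.2-fold of 1 ratio to the seminal vesicle in the post-meiotic library (7.17%) and 13 in the early pachytene library (0.3999%), while the other abundant transcripts had median ratios of 46.8% and 27.8%. If RNA of the seminal vesicle were mixed in, hardly any other abundant transcript could lie below that ratio, and 0.1% of 1000 did in the post-meiotic library and 2.532% of 395 in early pachytene. At the bound of the post-meiotic library, 15.4% to 40.4% lay below it in the 7 libraries other than spermatids, which had 0.5%, and at that of early pachytene 12.9% to 21.3% in the 6 libraries other than the post-meiotic region and spermatids, which had 0. Mixing may account for the low values of these transcripts in both libraries, but the low share in spermatids shows that a low share alone does not single it out. For the post-meiotic library, shared expression in neighbouring male tissue stays open. That does not apply to early pachytene, a female region, whose own expression of these transcripts was not tested. Late pachytene had a median ratio of 0.0395% for the same 21 transcripts. Whether mixing arose at dissection or between libraries is not known.

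In the seminal vesicle, 246 transcripts were listed at 0 with 10 RPKM or more in both neighbouring regions, and no such transcript was found in the 5 other inner regions. Other transcripts of the same genes with like values in both neighbours were above 0 in 100% of 217 cases, with a median of 24.4 RPKM. That median argues against levels too low for the depth. Failed estimates for single isoforms in this library are a candidate explanation, and a switch of isoforms stays open.

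Eliminated genes were mostly highest in the male mitotic region or spermatogenesis. Without the scaffold that carries mitochondrial genes the share was 73.721%, and with rescaled libraries 81.804%, both above the shares of retained genes (31.7% and 38.6%), which argues against these as the whole cause. Among genes whose annotation no other gene carries it was 71.154% (37 of 52, interval 56.9 to 82.9) against 25.5% of 2461 retained genes, which argues against reads shared within a named family. Near copies under other names stay open. A bias of eliminated genes toward the early male germline may be biological, as a hypothesis found and tested on the same data.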
